A study of Danio rerio with 4 samples.

How the data were processed

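Messenger RNA of ventricles from adult zebrafish, 24 h after cryoinjury and after heat shock at 39 °C, was sequenced in 2 WT and 2 Tg(hsp70l:sflt4) libraries. Per the labels, each library was made from a pool of 3 ventricles with 500 ng of total RNA and a stranded mRNA-seq kit (VAHTS, Vazyme), and the strain was AB. The submitters' processing notes name FastQC, Trimmomatic 0.38, featureCounts 1.6.3 of Subread, DESeq2 1.18.1 and the genome build danRer11, without role or order. The aligner is not given in the sources used here.

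The deposited table holds 1 value per gene and library for 17221 genes, 16701 of them protein coding, with Ensembl identifiers, danRer11 coordinates and annotation terms. Its unit is a score in the sense of a number that is neither a raw count nor a rate: the deposited values are read counts divided by a size factor per library and rounded to whole numbers. This follows from the table's own description as normalized and from the values, whose medians were 335, 332, 335 and 328 and whose median-of-ratios factors were between 1.0009 and 1.0017. The lowest mean over the 4 libraries in the table was 4.25, so genes with few reads had been left out before deposit. All value columns were mapped to samples through the sample titles.

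Rounding leaves a pattern in the frequency of whole numbers, and each library's size factor was estimated from it by maximum likelihood. On simulated tables with 5 known factors the largest error was 3e-05. The factors were 1.02 and 1.01 for WT replicates 1 and 2 and 1.10 and 0.885 for Tg(hsp70l:sflt4) replicates 1 and 2. They give about 34800000, 34300000, 33100000 and 29000000 reads counted in genes, against normalized totals of 34096403, 33799004, 30171847 and 32774116. In 3 of the libraries rounding merges neighbouring read counts, so whole reads could not be recovered and no count test was used. Counting error at this depth is small beside the spread of replicates: the squared difference of 2 libraries of a group over its counting variance averaged 75.3 per gene in WT and 70.3 in Tg(hsp70l:sflt4), with medians of 6.21 and 3.22. No 2 libraries of a group were alike enough to be the same library.

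The test planned first assumed raw counts. Since the values are normalized, the alternative fixed with it was used: limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend and robust moderation, for the 17071 genes with a mean of at least 10 over the 4 libraries. The fit held no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates those of low genes. The labels call each replicate a pool of ventricles and say nothing more about how the pools were formed, so p-values measure the spread between these samples. Mean values are given with the SD of 2 libraries, and intervals or floors, where given, cover counting error only.

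Gene groups were 29 lists of 771 symbols fixed before the data were examined, covering Vegfc and Notch signaling, the cell types a ventricle sample could hold, injury, inflammation, stress, cell cycle and metabolism. A row was found for 644 symbols, 16 of them through gene identifiers and a table of reference names, which held 16648 of the 17221 identifiers. Some genes stand in more than 1 list. Lists were tested with camera against all other genes at a preset inter-gene correlation of 0.01, two-sided, and adjusted over the 29 lists. The same test was run with a correlation estimated for each list, and fry tested whether a list's genes moved one way on balance or in either direction. The deposited annotation terms with 10 to 500 tested genes were tested with camera, 2705 in all.

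Named genes followed a rule fixed before the data were examined. It takes *flt4*, *vegfc*, *vegfd* and *hsp70l*, the genes *emilin2a*, *cxcl8a* and *cxcr1* that the study is known to have followed up, up to 4 members of each list with the smallest p, and among called genes with a plain symbol, a mean of at least 50 and no overlap between groups, per direction the 8 with the largest fold and 6 more with the smallest p. As no gene was called, the last part was applied to genes with an unadjusted p under 0.01, a change made after the values were seen. The text names part of these genes, and 1 item is not reported here.

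On values simulated for the real genes of this comparison, with 200 genes changed and noise independent between genes, limma recovered 88 of 100 genes changed 4-fold and 99 of 100 changed 16-fold, with 9 false calls among 16866 genes run. In a further simulation over 16834 genes, a list of 30 genes shifted by 0.8 (log2) was called and 0 of 200 unshifted lists were. The changed and shifted genes all had a mean of at least 100, so lower genes were not covered. Real libraries share deviations across genes, which the simulation leaves out. The recovered shares therefore do not carry over to the real libraries, and 0 calls there do not mean that 4-fold changes are absent.

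Alternatives were another scaling (upper quartile, median of ratios), no filter or a mean of at least 50, limma-voom, pseudocounts of 0.5 and 5, the replicate number as a block, stricter thresholds and leaving out each library. When a library was left out, its group had 1 library, which was assumed to vary like the other group. Scaling to equal totals, and further settings for the lists and terms, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the size factors and plots.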

Results

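Messenger RNA was sequenced from ventricles of adult zebrafish 24 h after cryoinjury, a local freezing injury that kills part of the heart muscle and from which the zebrafish heart regenerates. WT fish were compared with Tg(hsp70l:sflt4) fish, in which the *hsp70l* heat-shock promoter drives sflt4, a soluble form of the Vegfc receptor Flt4 that binds the ligand away from the cells. Fish of both groups were heat-shocked at 39 °C. Each group had 2 libraries, each made from a pool of 3 ventricles. The estimated number of reads counted in genes was about 34800000 and 34300000 in the WT libraries and 33100000 and 29000000 in the Tg(hsp70l:sflt4) libraries, and the gene table held 17221 genes. Mitochondrial genes took 19.5% and 18.8% of the normalized total in WT replicates 1 and 2, and 14.4% and 17.1% in Tg(hsp70l:sflt4) replicates 1 and 2. The design asks which transcripts of the injured ventricle depend on Vegfc signaling, and it implies 1 comparison, Tg(hsp70l:sflt4) against WT.

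Normalized read counts of *flt4* (chromosome 14, 15816509 to 15956921, danRer11) did not separate the groups: 618 and 515 in WT, 504 and 538 in Tg(hsp70l:sflt4). The log2 difference was -0.12 (SE 0.17, limma adjusted p = 0.823). The sequence of the transgene is not given in the sources used here, so *flt4* reads need not report it, and the groups below are those of the labels. The ligand gene *vegfc* gave 428 and 1077 in WT and 746 and 884 in Tg(hsp70l:sflt4), and *vegfd*, which encodes another Flt4 ligand, gave 61 and 44 against 42 and 31. Endogenous *hsp70l* gave 461 and 4264 in WT, a wider range than the 1191 and 647 of the transgenic libraries. Of the genes that the study is known to have followed up, which are not independent evidence here, *emilin2a* stood furthest apart. This gene for an elastin microfibril interface protein (chromosome 2, 30986996 to 31018096) had 2210 and 1244 normalized reads in WT and 449 and 268 in Tg(hsp70l:sflt4). That is 1727 ± 683 against 358.5 ± 128 (SD, n = 2 per group), or a log2 difference of -2.25 (SE 0.36, limma adjusted p = 0.272). The neutrophil-attracting chemokine gene *cxcl8a* gave 191 and 2679 in WT and 327 and 479 in Tg(hsp70l:sflt4), so the WT libraries lay on both sides of the transgenic ones. Its receptor gene *cxcr1* gave 131 and 251 against 242 and 386. None of these 7 genes passed the test.

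**Figure D1:**
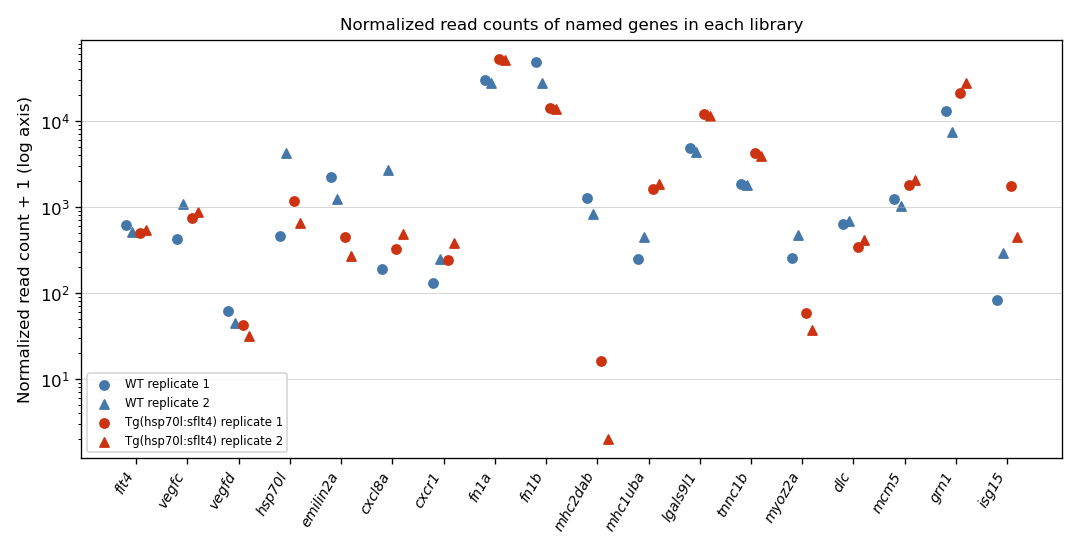
Normalized read count plus 1 (log axis) of 18 named genes in the 2 WT libraries (blue) and the 2 Tg(hsp70l:sflt4) libraries (red), circles for replicate 1 and triangles for replicate 2. The 4 values of *flt4* lie between 504 and 618 with no separation of the groups, while *emilin2a* is at 2210 and 1244 in WT and 449 and 268 in Tg(hsp70l:sflt4).

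Across the 17071 genes tested, limma called 0 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.154. At an unadjusted p under 0.05 there were 1881 genes, 951 higher and 930 lower in Tg(hsp70l:sflt4), where 5% of the tested genes would be 854. Scaling the libraries to equal totals turned that division into 1584 higher and 548 lower, and moved the median gene by 0.11 (log2) toward Tg(hsp70l:sflt4). The limma-voom test also called 0 genes, with 1839 at an unadjusted p under 0.05. The values of the 2 groups did not overlap for 7382 genes (43.2%), a share that chance alone puts at 33.3%. Libraries of the same group differed widely, with a pooled SD of log2 values of 0.51 in WT and 0.39 in Tg(hsp70l:sflt4). An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333. Leaving out a library changed the count: 250 genes were called without WT replicate 1, 75 without WT replicate 2, 3 without Tg(hsp70l:sflt4) replicate 1 and 0 without Tg(hsp70l:sflt4) replicate 2.

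Since no gene was called, the genes in this paragraph were chosen after their values were seen, by size of fold and by unadjusted p, and none passed the adjusted threshold. Transcripts for muscle proteins appeared on both sides. *mybpc2b*, a fast myosin-binding protein C gene (chromosome 24), was at 0 in both WT libraries and at 105 and 190 in Tg(hsp70l:sflt4), at least 49.2-fold higher against a floor of 3 counts per library. *tnnc1b*, a troponin C gene, was 2.22-fold higher (4092 ± 168 against 1843 ± 42.4, SD, n = 2, adjusted p = 0.179). *myoz2a*, a gene for a Z-disc protein, was lower at 57 and 36 against 257 and 473, and *lmod2a*, for an actin-filament nucleator of the sarcomere, was lower at 510 and 568 against 1170 and 1017. Immune genes with higher values in Tg(hsp70l:sflt4) included the galectin gene *lgals9l1* (12167 and 11588 against 4918 and 4405), the complement regulator *cfh* (871 and 807 against 368 and 315) and *c3a.4* (283 and 416 against 104 and 56). Its more abundant relative *c3a.1*, from the liver gene list, went the other way (644 and 859 against 1215 and 2021). *mhc1uba* and *mhc2dab*, each an antigen-presentation gene, went apart. The former was at 1601 and 1832 against 248 and 453, and the latter at 15 and 1 against 1276 and 820. Genes of the *mhc*, *c3a* and *dicp* families have close copies among which reads can be split, so their values are uncertain. Other genes with higher values were *col11a1a*, a fibrillar collagen (634 and 600 against 175 and 72), *tgfbi*, a matrix protein induced by Tgfb (1764 and 2224 against 786 and 600), and the lipid-droplet gene *plin2* (1111 and 2156 against 419 and 337). Lower values were seen for *ddit4*, a stress-induced inhibitor of mTORC1 (211 and 120 against 699 and 882), the beta-adrenergic receptor *adrb2b* (82 and 44 against 301 and 887), *igfbp1b*, an insulin-like growth factor binding protein (4 and 9 against 41 and 160), and the palmitoyltransferase *zdhhc2* (36 and 20 against 244 and 249).

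Of the 29 gene lists fixed before the data were examined, 9 were called by camera with a preset correlation of 0.01, 5 higher and 4 lower in Tg(hsp70l:sflt4). None of the 9 calls held with an estimated correlation, and fry's directional test called 0 lists, with a smallest adjusted p of 0.648. No member of any list passed over all genes tested. Adjusted over the list alone, 1 gene passed in each of 3 lists: *myoz2a* among sarcomere genes, *emilin2a* among emilin and elastic fibre genes and *mybpc2b* among skeletal muscle genes. The study is known to have followed up *emilin2a*, so its pass in a list of emilin genes is not independent evidence.

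Cell cycle genes rose in Tg(hsp70l:sflt4). Of 40 measured genes 39 had the higher mean in the transgenic libraries, 21 of them at an unadjusted p under 0.05, and the mean log2 difference was 0.79 (camera adjusted p = 7.1e-14, and adjusted p = 0.852 with an estimated correlation). The replication helicase genes *mcm2* (1859 and 1973 against 1239 and 954), *mcm4* (1876 and 2192 against 1379 and 1311) and *mcm5* (1810 and 2088 against 1226 and 1027) were 1.51-fold to 1.76-fold higher. The kinetochore gene *cenpf* was at 470 and 357 against 199 and 105. WT replicate 2 stood lowest, with a mean deviation of -0.80 from the genes' means over the 4 libraries, against 0.01 in WT replicate 1 and 0.55 and 0.25 in the transgenic libraries. The list's shift, its mean log2 difference minus that of all other genes, was 0.82, and it was 0.43 without WT replicate 2 and 1.1995 without WT replicate 1. The shift kept its direction without each library in turn. The correlation estimated between the list's genes was 0.58, against the preset 0.01, so the preset test took the genes as nearly independent. Among annotated gene sets, 100 of 2705 terms were called by camera, 95 higher and 5 lower in Tg(hsp70l:sflt4), led by the pathway term DNA replication (35 genes, mean log2 difference 0.42, adjusted p = 3.0e-07). None was called with an estimated correlation, where the adjusted p was 0.993, and 66 to 156 terms were called when single libraries were left out.

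Interferon response genes and macrophage and neutrophil markers rose in Tg(hsp70l:sflt4), with uneven levels among libraries of a group, while lymphocyte markers, inflammatory cytokines and chemokines did not pass the test. The interferon response list rose by a mean log2 difference of 0.91, with 27 of 31 genes higher (camera adjusted p = 9.2e-06, and adjusted p = 0.852 with an estimated correlation). Its mean deviation was 1.05 in Tg(hsp70l:sflt4) replicate 1, -0.14 in replicate 2, and -0.67 and -0.24 in WT. *isg15*, a ubiquitin-like protein gene induced by interferon, read 83 and 293 in WT and 1748 and 450 in Tg(hsp70l:sflt4), *ifit8* read 12 and 11 against 453 and 49, and *mxa* 503 and 579 against 2342 and 845. *socs1a*, a feedback inhibitor of cytokine signaling, was more even at 674 and 646 against 1103 and 1376. The list lost its call without WT replicate 1 (adjusted p = 0.0627), and its shift against other genes, 0.94 with all libraries, was 0.37 without Tg(hsp70l:sflt4) replicate 1. Macrophage markers rose by a mean of 0.27, with 22 of 28 genes higher (adjusted p = 0.0095, and adjusted p = 0.852 with an estimated correlation). Among them were the granulin gene *grn1* (21140 and 27956 against 13171 and 7444) and the macrophage transcription factor gene *irf8* (1845 and 2245 against 1232 and 1358). Their mean deviation was -0.26 and -0.01 in WT and -0.03 and 0.29 in Tg(hsp70l:sflt4), and the call ended without WT replicate 1 (adjusted p = 0.401) or Tg(hsp70l:sflt4) replicate 2 (adjusted p = 0.247). Neutrophil markers rose by 0.17, with 14 of 19 genes higher (adjusted p = 0.0485, and adjusted p = 0.852 with an estimated correlation). Against the direction of the list, *lyz*, for lysozyme, read 12 and 6 against 38 and 29. The neutrophil call ended without WT replicate 1 (adjusted p = 0.254), and without Tg(hsp70l:sflt4) replicate 2 the list's shift against other genes, 0.19 with all libraries, was -0.01. The call also ended with equal totals (adjusted p = 0.0503) and a pseudocount of 5 (0.0503), while at a mean of at least 50 the shift was 0.29 (0.0141).

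Immediate early genes rose by a mean log2 difference of 0.22 in Tg(hsp70l:sflt4), with 23 of 31 higher (camera adjusted p = 0.0095, and adjusted p = 0.852 with an estimated correlation). The stress transcription factor gene *atf3* was at 4193 and 4356 against 1481 and 2779. WT replicate 1 was low for this list, at a mean deviation of -0.49, and WT replicate 2 was the highest library at 0.27. Without WT replicate 1 the shift turned to -0.16 (adjusted p = 0.946), and without Tg(hsp70l:sflt4) replicate 1 the adjusted p was 0.0827.

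Sarcomere genes of heart muscle fell in Tg(hsp70l:sflt4). The list had 19 of 23 genes lower, with a mean log2 difference of -0.38 (camera adjusted p = 0.0095, and adjusted p = 0.852 with an estimated correlation). Fry's test for change in either direction gave an adjusted p of 0.0031, and its directional test gave 0.730. Abundant members were *myl7*, a cardiac myosin light chain gene (204313 and 245157 against 335222 and 316610), and *myh7l*, a myosin heavy chain gene (404577 and 437436 against 703025 and 527025). The Z-disc gene *ldb3b* read 21471 and 24932 against 46373 and 36705. Both WT libraries lay above both transgenic ones for this list (mean deviations 0.27 and 0.11 against -0.20 and -0.17), as they did for the share of mitochondrial genes (19.5% and 18.8% against 14.4% and 17.1%). The call ended without WT replicate 1, with an adjusted p of 0.400. Notch pathway genes fell by a mean of 0.27 on the log2 scale, with 14 of 19 lower (adjusted p = 0.0485, and adjusted p = 0.852 with an estimated correlation). For this list fry's test for either direction gave an adjusted p of 0.0094, and its directional test gave 0.648. The ligand gene *dlc* read 346 and 416 against 638 and 692, the target gene *hey1* 54 and 60 against 128 and 93, and the Fringe gene *lfng* 2312 and 2458 against 3007 and 4063. Another Fringe gene, *mfng*, was higher at 1381 and 1393 against 1036 and 959. The Notch call ended without WT replicate 1 (adjusted p = 0.311), Tg(hsp70l:sflt4) replicate 1 (0.0827) or Tg(hsp70l:sflt4) replicate 2 (0.0767), and with equal totals (0.0503), a pseudocount of 5 (0.0503) or a mean of at least 50 (0.0726). Glycolysis genes fell by a mean of 0.24, with 29 of 37 lower (adjusted p = 0.0485, and adjusted p = 0.852 with an estimated correlation). *slc2a1a*, a glucose transporter gene, read 223 and 87 against 278 and 408. Without WT replicate 1 the adjusted p was 0.393, and without Tg(hsp70l:sflt4) replicate 2 it was 0.541. It was 0.0593 with upper-quartile scaling, 0.0571 with equal totals and 0.0503 with a pseudocount of 5. Erythrocyte genes fell by a mean of 0.31, with 15 of 19 lower (adjusted p = 0.0485, and adjusted p = 0.852 with an estimated correlation). Their mean deviation was 0.33 and -0.01 in WT and -0.36 and 0.04 in Tg(hsp70l:sflt4), and without Tg(hsp70l:sflt4) replicate 1 the adjusted p was 0.416 and without WT replicate 1 it was 0.3801. The list's shift against other genes, -0.29 with all genes tested, was -0.15 at a mean of at least 50, where the call ended (adjusted p = 0.125), as it did with a pseudocount of 5 (0.0503).

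**Figure D2:**
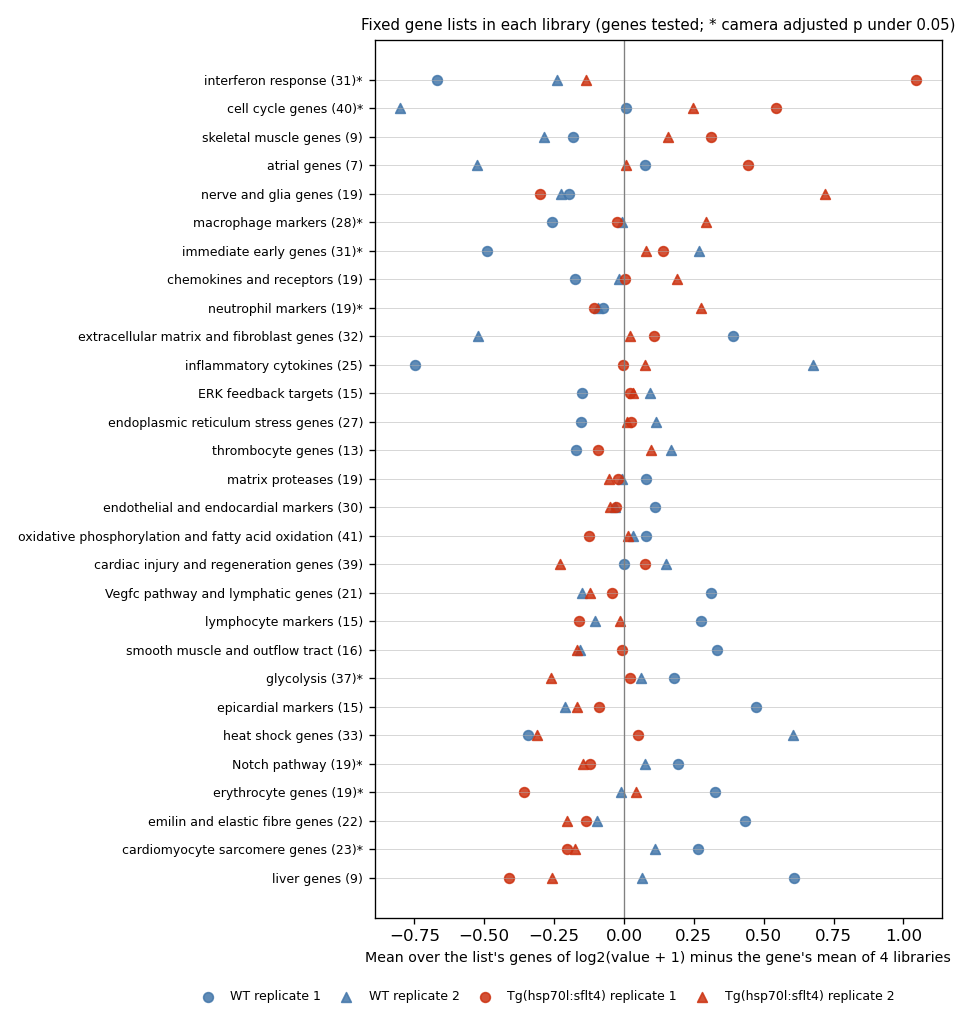
Mean over each list's genes of log2(value + 1) minus the gene's mean over the 4 libraries, for the 29 fixed lists, with the number of genes tested in brackets and an asterisk where camera's adjusted p was under 0.05 at the preset correlation. WT libraries are blue and Tg(hsp70l:sflt4) libraries red, circles for replicate 1 and triangles for replicate 2. Interferon genes reach 1.05 in Tg(hsp70l:sflt4) replicate 1 and -0.14 in replicate 2, and cell cycle genes are at -0.80 in WT replicate 2.

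Matrix and epicardial genes gave no call as lists in the main test of all 4 libraries. Emilin and elastic fibre genes had a mean log2 difference of -0.34, with 15 of 22 lower (adjusted p = 0.0534). Beside *emilin2a*, *emilin1b* read 1132 and 1125 against 1648 and 1465, and *fbln1*, a fibulin gene, 23 and 35 against 85 and 85. Another member, *mfap4*, was higher at 7286 and 8325 against 3721 and 5525. Epicardial markers had a mean of -0.26 (adjusted p = 0.0555), and the epicardial transcription factor gene *tcf21* read 426 and 332 against 783 and 451. Extracellular matrix and fibroblast genes had a mean of 0.13 (adjusted p = 0.264), and the fibronectin paralogues went apart. *fn1a* read 52814 and 51356 against 29732 and 27803, and *fn1b* 14251 and 13656 against 48333 and 27526. Whether reads were split between these paralogues was not checked here, so their values are uncertain. The injury-induced matrix gene *tnc* read 933 and 818 against 521 and 168. Matrix proteases had a mean of -0.07 (adjusted p = 0.996), and smooth muscle and outflow tract genes -0.18 (adjusted p = 0.355). WT replicate 1 stood high for several of these lists, with a mean deviation of 0.47 for epicardial markers, 0.43 for elastic fibre genes and 0.39 for matrix and fibroblast genes. With the libraries scaled to equal totals the elastic fibre list was called lower (shift -0.31, adjusted p = 0.0290). Without WT replicate 2 the shift was -0.56 for elastic fibre genes, -0.56 for epicardial markers, -0.38 for smooth muscle genes and -0.28 for matrix and fibroblast genes. Without WT replicate 1 these shifts were -0.07, 0.08, 0.07 and 0.59, in that order. The direction for epicardial, smooth muscle, and matrix and fibroblast genes thus depended on which WT library was kept.

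Lists closest to the receptor gave no call in the main test of all 4 libraries. Vegfc pathway and lymphatic genes had a mean log2 difference of -0.16, with 16 of 21 lower (adjusted p = 0.125). *kdrl*, which encodes a Vegf receptor, read 8563 and 7287 against 11024 and 9678, and the lymphatic transcription factor gene *prox1a* 847 and 783 against 1158 and 893. Going the other way, *stab2* read 1127 and 1288 against 1053 and 433, and *tfec* 354 and 398 against 306 and 296. Endothelial and endocardial markers had a mean of -0.08 (adjusted p = 0.463). ERK feedback targets had a mean of 0.06 (adjusted p = 0.767), with members on both sides. *dusp6* read 5780 and 5969 against 7185 and 8306 and *spry2* 789 and 725 against 944 and 1012, while *dusp5* read 1894 and 1558 against 737 and 1022. Without WT replicate 2 the shift of the Vegfc pathway list was -0.35, and without WT replicate 1 it turned to 0.07. The direction of this list thus depended on which WT library was kept.

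The remaining lists were not called by camera. Oxidative phosphorylation and fatty acid oxidation genes had a mean log2 difference of -0.11 (adjusted p = 0.0502), liver genes -0.67 (0.0819), nerve and glia genes 0.42 (0.0983), atrial genes 0.45 (0.125), and cardiac injury and regeneration genes -0.15 (0.213). Chemokines and receptors had a mean of 0.19 (adjusted p = 0.264), with the chemokine gene *cxcl8b.1* at 254 and 232 against 141 and 122 and *ccl25b* at 366 and 365 against 1130 and 589. Inflammatory cytokines had a mean of 0.07 (adjusted p = 0.467), heat shock genes -0.26 (0.359) and endoplasmic reticulum stress genes 0.04 (0.742). The mean, median and test differed in sign for skeletal muscle genes (mean 0.47, median -0.32, adjusted p = 0.708 in the lower direction), where *mybpc2b* carried the mean, and fry's test for change in either direction passed them with an adjusted p of 0.0227. They also differed for lymphocyte markers (mean -0.17, median 0.01, 0.971) and thrombocyte genes (mean 0.004, median -0.08, 0.971). At a mean of at least 50, liver genes (shift -1.27, adjusted p = 0.0141) and oxidative phosphorylation genes (-0.10, 0.0410) were called lower. Leaving out 1 library also called some of these lists. They were, without WT replicate 1, inflammatory cytokines (shift -0.64, adjusted p = 0.00017) and heat shock genes (-0.74, 0.0014), and without WT replicate 2, inflammatory cytokines in the other direction (0.83, 1.15e-06), endoplasmic reticulum stress genes (0.22, 0.0328), oxidative phosphorylation genes (-0.09, 0.0497) and liver genes (-0.90, 0.0388). Without Tg(hsp70l:sflt4) replicate 1, nerve and glia genes were called higher (0.98, 0.00071) and cardiac injury genes lower (-0.26, 0.0265). Without Tg(hsp70l:sflt4) replicate 2, atrial genes were called higher (0.68, 0.0041), and oxidative phosphorylation (-0.17, 0.00021) and liver genes (-0.82, 0.0399) lower.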

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

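Scaling to equal totals, and the upper-quartile and pseudocount settings for lists, were chosen after seeing the data. No gene was called under upper-quartile, median-of-ratios or total scaling, without a filter, at a mean of at least 50, with limma-voom, with pseudocounts of 0.5 or 5, or at the stricter thresholds. Without single libraries, between 0 and 250 genes were called, 0 to 121 higher and 0 to 129 lower in Tg(hsp70l:sflt4). At an unadjusted p under 0.05, between 327 and 1392 genes were higher and between 366 and 1389 lower, and equal totals gave 1584 higher and 548 lower, by the construction of that scaling, which moves the median gene by 0.11. The other 2 divisions of the 4 libraries into pairs gave 688 and 228 genes at that level and called 0. With 3 divisions no share can be under 0.05.

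With the replicate number as a block, 0 genes were called, as without it. The labels do not say that a number marks a shared batch, and deviations of same-numbered libraries correlated at 0.137 across genes with 2 pairs. With the block 13 lists were called, the 9 called without it among them. The planned tests on raw counts were not run, since the values are not counts, and the recomputed median-of-ratios factors moved no call.

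With an estimated correlation 0 lists and 0 terms were called, and fry's directional test called 0 lists. The shifts of the 9 lists against other genes are unchanged there by construction (0.82 cell cycle, 0.94 interferon, 0.29 macrophage, -0.36 sarcomere, 0.24 immediate early, 0.19 neutrophil, -0.24 Notch, -0.29 erythrocyte, -0.22 glycolysis). A pseudocount of 5 called 5 lists, losing Notch (-0.23), neutrophil (0.21), erythrocyte (-0.26) and glycolysis genes (-0.22). Upper-quartile scaling lost glycolysis (-0.22). Equal totals lost Notch (-0.24), neutrophil (0.19) and glycolysis genes (-0.22). A mean of at least 50 lost Notch (-0.20) and erythrocyte genes (-0.15). Lists not called in the main test were gained, all lower in Tg(hsp70l:sflt4). Upper-quartile scaling gained oxidative phosphorylation genes (-0.088, adjusted p = 0.0448), as did a pseudocount of 0.5 (-0.089, 0.0498). Equal totals gained elastic fibre (-0.31, 0.0290) and liver genes (-0.65, 0.0290), and a mean of at least 50 gained oxidative phosphorylation (-0.10, 0.0410) and liver genes (-1.27, 0.0141). The replicate block gained elastic fibre (-0.31, 0.0375), epicardial (-0.24, 0.0427), oxidative phosphorylation (-0.088, 0.0427) and liver genes (-0.65, 0.0155). The causes were not tested.

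Without single libraries, 4 to 18 lists and 66 to 156 terms were called. The shift of called lists ranged from 0.37 to 1.51 for interferon, 0.064 to 0.47 for macrophage, -0.41 to -0.30 for sarcomere, -0.16 to 0.64 for immediate early, -0.011 to 0.40 for neutrophil, -0.28 to -0.21 for Notch, -0.50 to -0.068 for erythrocyte and -0.34 to -0.089 for glycolysis genes. Lists that were not called and changed sign ranged from -0.35 to 0.071 (Vegfc pathway), -0.063 to 0.22 (ERK targets), -0.28 to 0.59 (matrix and fibroblast), -0.56 to 0.083 (epicardial), -0.26 to 0.0080 (cardiac injury), -0.32 to 0.018 (lymphocyte), -0.64 to 0.83 (inflammatory cytokines), -0.17 to 0.22 (thrombocyte), -0.74 to 0.26 (heat shock), -0.094 to 0.22 (endoplasmic reticulum stress), -0.17 to 0.0027 (oxidative phosphorylation), -0.38 to 0.071 (smooth muscle) and -0.10 to 0.98 (nerve and glia). Of 59 genes named in the text and compared under other settings, 4 changed sign: the log2 difference ranged from -0.25 to 0.016 for *flt4*, -0.41 to 0.92 for *vegfc*, -2.28 to 0.93 for *hsp70l* and -2.76 to 1.05 for *cxcl8a*. Of the 765 values of the 59 genes under other settings, 733 kept direction and side of the threshold and 28 passed it. With 1 library left in a group, only the 2 libraries of the other group set the spread. Leaving out a WT library thus kept the narrower spread of Tg(hsp70l:sflt4) (pooled SD 0.39). Leaving out a transgenic library kept the wider one of WT (0.51). No other cause was tested.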

Other observations

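The tests below were chosen after the values were seen, except those of the gap between marker lists and of neighbour pairs among 512 genes. The WT libraries differed from each other in the mean of inflammatory cytokine genes by more than either differed from the transgenic libraries, with mean deviations of -0.75 in WT replicate 1 and 0.68 in WT replicate 2 against -0.005 and 0.08 in Tg(hsp70l:sflt4). Heat shock genes were at -0.34 and 0.61 in WT and 0.05 and -0.31 in Tg(hsp70l:sflt4), with *hsp90aa1.1* at 24603 and 59627 against 24555 and 6084. Nerve and glia genes stood apart in Tg(hsp70l:sflt4) replicate 2, at 0.72 against -0.20 to -0.30 in the other libraries. Among terms lower in Tg(hsp70l:sflt4) was artery development (18 genes, mean log2 difference -0.28, camera adjusted p = 0.0318, and adjusted p = 0.993 with an estimated correlation). Among terms called higher were phagosome (124 genes, 0.17, adjusted p = 0.0450) and positive regulation of innate immune response (12 genes, 0.55, adjusted p = 0.0430), each with adjusted p = 0.993 at an estimated correlation, while innate immune response (58 genes) was not called (adjusted p = 0.0798).

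Interferon genes were high in Tg(hsp70l:sflt4) replicate 1, at a mean deviation of 1.05 against -0.14 in replicate 2 and -0.67 and -0.24 in WT. More leukocytes in replicate 1 would raise leukocyte markers alike. The mean log2 difference of these markers from the other libraries was instead -0.11. Minus that of interferon genes it was -1.505 (SE 0.26 over genes, which are not independent). An antiviral response in fish of this pool and an effect of the transgene both stay open, and neither was tested.

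Cell cycle genes were higher in Tg(hsp70l:sflt4). Without WT replicate 2, the lowest library, the mean log2 difference was 0.39 (SE 0.06 over genes), and against WT replicate 2 alone it was 1.195. The spread between libraries of a group gives 2 libraries against 1 an SE of 0.53, so the low level of WT replicate 2 alone cannot be told apart from a difference between the groups. A lower share of heart muscle cells would raise markers of the other cell types alike, and as the whole cause by as much as the cell cycle genes. Macrophage markers, the highest of 6 lists, exceeded epicardial markers, the lowest, by 0.53 (SE 0.13 over genes, without allowance for picking extremes). This gap was 0.06, 0.99, 0.73 and 0.33 without WT replicates 1 and 2 and Tg(hsp70l:sflt4) replicates 1 and 2, where the gap between the highest and lowest of the 6 lists was 0.59, 0.99, 0.73 and 0.39. The 139 markers of 6 cell types had a mean log2 difference of 0.04 against 0.79 for cell cycle genes, a shortfall of -0.75 (SE 0.07 over genes, 0.30 from the spread between libraries) that ranged from -0.99 to -0.51 without single libraries. The markers thus rose by less than a lower share of heart muscle cells, as the whole cause of the cell cycle difference, would give. With 2 libraries per group the SE from their spread is itself uncertain, so that explanation is not excluded. For the fall of sarcomere genes, beside which mitochondrial genes had a lower share in both transgenic libraries, that explanation was not tested and stays open. Proliferation of 1 cell type, such as leukocytes, or a difference between the injuries may account for the pattern, and the transgene stays open as untested.

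With a cut chosen after the values were seen, a sum of at most 4 normalized reads over the libraries of 1 group and at least 30 in each library of the other, 13 genes were nearly absent from 1 group, among them *mybpc2b*, *cryaa* and *ggact.3* in WT. They lie on 9 chromosomes, which goes against linkage to 1 transgene insertion. Haplotypes that swap neighbouring genes would give neighbours within 100 kb that go opposite ways. Among 512 genes with an unadjusted p under 0.01 there were 11 such pairs, where random assignment gave a median of 15 and a 95th percentile of 22. That test was first set for haplotypes in general, and was narrowed to swapped neighbours after the count was seen. It would miss swaps over more than 100 kb. On chromosome 8, *CU929676.1* (36268747 to 36292840) read 85 and 179 in Tg(hsp70l:sflt4) and 0 and 1 in WT. Further along, *mhc2dab* (36466771 to 36469117) went the opposite way, at 15 and 1 against 1276 and 820. This pair was picked after the values were seen, and swapped haplotypes stay open. Neighbours going the same way were in excess, 36 pairs against 22 at that percentile (one-sided permutation p = 1e-04, the smallest that 10000 draws can give), and 5 of the 13 genes had a neighbour of unadjusted p under 0.01, in either direction, where the 95th percentile of random draws was 3 (one-sided permutation p = 0.01). Haplotypes that differ between the fish of the 2 groups and tandem genes regulated together may both give neighbours that go the same way. They cannot be separated without genotypes, and overlapping genes were not set aside.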
